A study of Danio rerio with 10 samples.

How the data were processed

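RNA from kidney marrow was labelled with biotin and hybridised to Affymetrix zebrafish arrays prepared with the 3' IVT Express kit, per the labels' protocols. There were 5 arrays from fish overexpressing human CREB and 5 from control fish, 5 animals per group per the series' design text, and groups were taken from the sample labels. The values used were the authors' deposited processed table of 15617 probe sets on 10 arrays. Its unit was read as log2 from the deposited values alone, which lie between 2.57 and 15.04 among the probe sets tested. The summary and normalization method is not given in the sources used here, so the scaling between arrays stays unknown. Array medians (5.72 to 5.93) and quartiles are close but not equal, and no centring per gene was seen.

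The 115 Affymetrix control probe sets were set aside, which left 15502. Gene symbols came from the platform annotation, updated through the Entrez gene ID with a RefSeq gene table of the assembly GRCz12tu, used for names only. One symbol was found for 10795 probe sets (10711 matched by the ID, 84 kept as annotated), several for 135 and none for 4572, which are unnamed here. The named probe sets cover 8793 genes. Where a gene had several probe sets, the one with the highest mean over the 10 arrays stood for it. Of 25 named genes with several probe sets, 16 had probe sets that differed in whether they passed, and 3 had probe sets of opposite direction.

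Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 15502 probe sets, threshold 0.05) with no filter and no covariate. Differences are CREB minus control on the log2 scale. Single values per array were compared with an exact two-sided permutation test over 252 arrangements, which cannot give a p below 0.00794. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and figures.

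The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Of 26 lists, 25 had at least 5 measured genes and were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over 25 lists). Of the members matched, 6 that shared only a name or pattern with the intended gene were left out. Lists may share genes: 9 of the 42 CREB target and immediate-early genes stand in another list. Named genes were the 12 largest rises and the 12 largest falls with adjusted p under 0.05 and no overlap between the groups, up to 4 members with the smallest p of each list described, and creb1a, cebpa, cebpb, cebpd, spi1b, mpx, lyz, gata1a, myb and pcna. Clone names were passed over.

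The alternatives were a replicate block, removal of dim probe sets (the dimmest 40%, or a mean below log2 6), quantile, median and cyclic loess scaling, eBayes with trend and robust settings, array weights, leaving out each array, an estimated correlation or fry for the lists, and the mean of a gene's probe sets. Leaving out arrays with egg or pancreas transcripts or a low gapdh 5' signal, and the permutation of list levels, were added after seeing the data. So were 2 lists, of muscle and glucocorticoid-responsive genes. They were first matched by symbol alone and then, with the result seen, by synonyms as for the other lists.

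The fit was tested on simulated data with the means and spreads of the 15502 probe sets and 200 changed in the comparison of CREB with control. It recovered 52.0% of changes of 1 and 91.0% of changes of 2 on the log2 scale, called 11 unchanged probe sets, and called 0 when nothing was changed. Camera found the 1 shifted list and none of the others when genes were simulated as independent, which real genes are not. With the preset correlation, 66 of 100 splits of the real arrays gave 8 or more called lists, so such a call decides nothing by itself.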

Results

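Whole-tissue RNA of kidney marrow, the main blood-forming organ of the adult zebrafish, was measured on a zebrafish oligonucleotide array. The arrays came from 5 fish overexpressing human CREB, a transcription factor activated by cyclic AMP signalling, and from 5 control fish. The study asked how raised CREB changes gene expression in marrow in which myeloid maturation is thought to be blocked. Each array gave 1 log2 signal for each of 15502 probe sets tested. Array medians lay between 5.72 and 5.93, and Pearson's r between pairs of arrays, across probe sets, lay between 0.818 and 0.981. With 5 arrays per group the number of arrays limits the precision of each value.

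The zebrafish gene creb1a, given first because CREB was the gene introduced, had a log2 signal of 6.80 ± 0.32 (SD, n = 5) in CREB fish and 6.97 ± 0.36 (SD, n = 5) in control fish. The difference of -0.18 ± 0.21 (SE) did not pass the test (limma, adjusted p = 0.519). The probe set was designed on the zebrafish transcript, so it does not check the level of the human transgene. The paralogue creb1b was not measured by a probe set with a single gene symbol.

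CREB target and immediate-early genes were higher in CREB fish. Of 42 measured members of that group, 27 rose, none fell and 15 did not pass the test, and 29 rose when adjusted over the list alone. The count was 9 without control arrays 3, 4 and 5, which leaves 2 control arrays, and the median log2 difference went from 1.02 to 0.85. The gluconeogenic enzyme gene pck1, a known cyclic AMP target, rose from 3.83 ± 0.23 to 9.63 ± 0.96 (SD, n = 5 each; limma, adjusted p = 0.000149). Its signal in control fish was no higher than that of control probe sets for tag sequences (4.08), so no fold is given. The clock gene per2 rose by 2.49 ± 0.19 on the log2 scale (SE), the AP-1 subunit gene jun by 2.61 ± 0.21 and the stress-response gene gadd45ba by 2.33 ± 0.22 (limma, adjusted p = 0.000221, 0.000246 and 0.000592). In all 4 genes the lowest CREB array lay above the highest control array. A second probe set each of jun and gadd45ba, with log2 differences of 0.95 and 0.80, did not pass. The steroid-receptor co-chaperone gene fkbp5, outside the list, rose 21.0-fold (limma, adjusted p = 0.000123). The mean level of the group was 8.03 ± 0.29 in CREB fish and 6.74 ± 0.17 in control fish (SD, n = 5 each; exact permutation p = 0.00794, the smallest that 5 against 5 allows, adjusted 0.0661 over 25 lists). Its median log2 difference lay 0.85 above that of all probe sets (limma camera with a preset correlation, adjusted p = 1.99e-09). With an estimated correlation the camera p was 0.0522 (adjusted p = 0.551).

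Clock genes moved in the same comparison, with 14 of 27 members higher, 2 lower and 11 not passing, and the counts were the same adjusted over the list alone. Besides per2, which both lists hold, the repressors bhlhe41 and bhlhe40 rose by 2.54 ± 0.33 and 1.44 ± 0.23 on the log2 scale (SE; limma, adjusted p = 0.00218 and 0.00424). The group's mean level was 6.82 ± 0.10 against 6.34 ± 0.06 (SD, n = 5 each; exact permutation p = 0.00794, adjusted 0.0661). Its median log2 difference of 0.34 lay 0.16 above that of all probe sets (limma camera, adjusted p = 0.0240; p = 0.0531 and adjusted p = 0.551 with an estimated correlation). That median was no larger than the rise of 0.39 in the remaining control probe sets, and background was not tested as a cause for this list. Of its 14 members with a mean of log2 6 or more, 8 were higher and 1 was lower. Without CREB arrays 3 and 5 the median was 0.40 and the camera call was lost with fewer arrays (adjusted p = 0.0544; from 0.00261 to 0.0544 over the camera alternatives with the preset correlation). Only 2 members passed without control arrays 3, 4 and 5, where the median was 0.28.

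**Figure D1:**
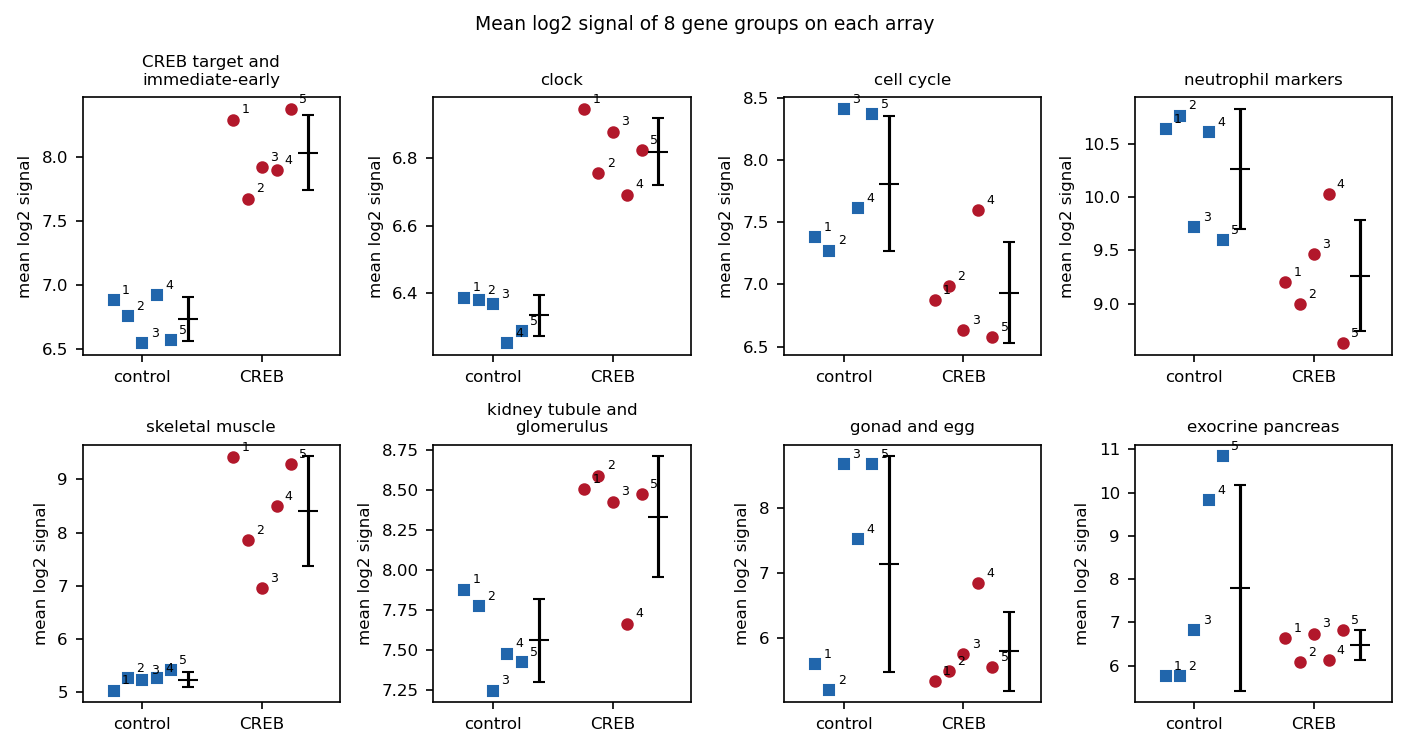
Mean log2 signal (y axis) of 8 gene groups on each array, by group (x axis); points are arrays numbered by replicate, and the bar at the right of each group gives the mean and SD of 5 arrays. The 5 CREB arrays lie above the 5 control arrays for CREB target and immediate-early, clock and skeletal muscle genes, and control arrays 3, 4 and 5 have the highest gonad and egg levels, at 8.67, 7.51 and 8.67.

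Transcripts of skeletal muscle gave the largest rises of any gene group. Of 18 measured muscle genes 15 rose and 3 did not pass, and 17 rose adjusted over the list alone. The count was 6 without control arrays 3, 4 and 5, where the median log2 difference went from 4.09 to 4.21. The parvalbumin genes pvalb3, pvalb2, pvalb1 and pvalb4, which encode calcium buffers of fast fibres, rose by 5.95 ± 0.58, 5.76 ± 0.49, 5.43 ± 0.56 and 5.07 ± 0.999 on the log2 scale (SE; limma, adjusted p between 0.000363 and 0.00820). In control fish pvalb4, at 4.52 ± 0.32 (SD, n = 5), was near the level of the remaining control probe sets (4.36 ± 0.09), which limits the size of its rise. The creatine kinase genes ckmb and ckma rose 31.3-fold and 30.3-fold, the troponin gene tnnt3b 27.7-fold, the myosin light chain gene mylz3 24.5-fold and the calcium pump gene atp2a1l 23.2-fold. All 9 genes were free of overlap between the groups, which the rule for the largest rises required. The group's mean level was 9.42, 7.86, 6.96, 8.50 and 9.29 on CREB arrays 1 to 5 and between 5.03 and 5.41 on the control arrays (exact permutation p = 0.00794, adjusted 0.0661). Camera called the group (limma, adjusted p = 1.84e-09), and the call was lost with an estimated correlation (p = 0.0661, adjusted p = 0.551).

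Kidney tubule and glomerulus genes were also higher in CREB fish, with 14 of 27 members past the test, none lower and 16 higher adjusted over the list alone. The phosphate transporter gene slc20a1a rose by 4.17 ± 0.39 on the log2 scale, the channel kinase gene trpm7 by 2.21 ± 0.31, the neutral amino acid transporter gene slc6a19a.1 by 2.12 ± 0.38 and the nephron transcription factor gene pax2a by 1.40 ± 0.25 (SE; limma, adjusted p between 0.000554 and 0.00605). The aromatic amino acid decarboxylase gene ddc, among the largest rises over all genes, went from 6.50 ± 1.06 to 10.94 ± 1.69 (SD, n = 5 each; limma, adjusted p = 0.00612). Its second probe set, with a log2 difference of 2.15, did not pass, and neither did a second probe set each of trpm7 and pax2a. The group's mean level was 8.33 ± 0.38 against 7.56 ± 0.26 (SD, n = 5 each; exact permutation p = 0.0238, adjusted 0.113), with CREB array 4 at 7.67 and the other CREB arrays between 8.43 and 8.59. The camera call (limma, adjusted p = 0.00143) was lost with an estimated correlation (p = 0.254, adjusted p = 0.906). It was also lost without control arrays 3, 4 and 5, where the median went from 0.75 to 0.49 and 1 member passed (adjusted p = 0.0852; from 2.08e-05 to 0.0852 over the camera alternatives with the preset correlation). Under cyclic loess 8 members passed.

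Cell cycle genes were lower in CREB fish: 34 of 81 members fell, 2 rose and 45 did not pass, and 37 fell adjusted over the list alone. The cytokinesis gene anln fell by 1.44 ± 0.21 on the log2 scale, the kinase gene cdk2 by 1.51 ± 0.23, the replication gene rpa2 by 0.76 ± 0.13 and the kinetochore gene ndc80 by 1.36 ± 0.24 (SE; limma, adjusted p between 0.00332 and 0.00559). The replication clamp gene pcna fell by 0.55 ± 0.16 (limma, adjusted p = 0.0314), a call lost when any of control arrays 1, 2, 4 and 5 or CREB arrays 1, 3 and 5 was left out (adjusted p up to 0.0651). The group's mean level was 6.93 ± 0.41 against 7.81 ± 0.54 (SD, n = 5 each; exact permutation p = 0.0238, adjusted 0.113). The median log2 difference lay at -1.11 relative to all probe sets (limma camera, adjusted p = 1.61e-13; p = 0.143 and adjusted p = 0.891 with an estimated correlation). Control arrays 3, 4 and 5, which carried gonad and egg transcripts, had the highest cell cycle levels of the control arrays, at 8.41, 7.61 and 8.37, against 7.38 and 7.27 on control arrays 1 and 2. Of the CREB arrays, array 4, with the highest gonad and egg level, had the highest cell cycle level, at 7.60 against 6.57 to 6.98. Without control arrays 3, 4 and 5 no cell cycle gene passed the test and the median difference was -0.32. Camera kept its call (limma camera with a preset correlation, adjusted p = 5.41e-05). That call decides nothing here, since with this setting 66 of 100 splits of the arrays gave 8 or more called lists. Without CREB arrays 3 and 5, 14 members were lower, and pcna was at -0.36 (adjusted p = 0.134).

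Gonad and egg genes and exocrine pancreas genes varied mainly among the control arrays. The yolk protein gene vtg3 fell by 2.25 ± 0.56 on the log2 scale (SE; limma, adjusted p = 0.0173), the only 1 of 18 gonad and egg members past the test, also adjusted over the list alone. The group's level was between 5.20 and 5.60 on control arrays 1 and 2, and 6.84 on CREB array 4 against 5.33 to 5.76 on the other CREB arrays. The gene vtg3 followed that level only in part. It was at 6.94 on control array 2, near its 6.84 on control array 3, and at 4.71 on CREB array 4. Of 14 pancreas genes, the disulfide isomerase gene pdia2 fell by 3.14 ± 0.54 and cuzd1.1 rose by 0.93 ± 0.19 (SE; limma, adjusted p = 0.00536 and 0.00991). In CREB fish pdia2 and vtg3, at 4.35 and 4.64, were at the level of control probe sets (4.33 for tag sequences, 4.76 for the remaining ones), which limits the size of both falls. In the pancreas list the counts were the same adjusted over the list alone. The pancreas level was 9.82 and 10.84 on control arrays 4 and 5 and between 5.75 and 6.83 on the other 8 arrays. Neither pdia2 nor cuzd1.1 followed that level. On control array 1, where the level was 5.75, pdia2 was at 9.03, against 8.20 and 7.51 on control arrays 4 and 5. The gene cuzd1.1 was at 5.19 on control array 1 and at 5.38 and 5.16 on control arrays 4 and 5. Camera called both groups lower (limma, adjusted p = 0.0407 and 0.0472), and both calls were lost with an estimated correlation (p = 0.385 and 0.454, adjusted p = 0.926 for both) and under each of 3 other scalings. They were also lost with 1 array left out, the pancreas call without control array 4 or 5 or CREB array 1, 2 or 4 (adjusted p up to 0.284), the gonad and egg call without control array 3, 4 or 5 or CREB array 1 or 2 (adjusted p up to 0.135). Without control arrays 3, 4 and 5 the medians turned positive, at 0.47 for gonad and egg genes and 0.996 for pancreas genes, and camera called pancreas genes higher (adjusted p = 0.00136). There vtg3 was at -1.14 and did not pass (adjusted p = 0.193).

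Neutrophil markers were lower: 4 of 11 members fell, 7 did not pass, and adjusted over the list alone 5 fell and 1 rose. The leukotriene pathway gene alox5ap had a log2 difference of -1.89 ± 0.35, the granule exocytosis gene vamp8 of -1.52 ± 0.31 and the granule proteoglycan gene srgn of -2.44 ± 0.66 (SE; limma, adjusted p = 0.00712, 0.00891 and 0.0227). Without CREB arrays 3 and 5 srgn was at -1.32 (adjusted p = 0.0405). The lysozyme gene lyz fell from 14.07 ± 0.22 to 13.48 ± 0.35 (SD, n = 5 each; limma, adjusted p = 0.0336). That call was lost when any of control arrays 1, 2 and 4 or CREB arrays 1, 2 and 5 was left out (adjusted p up to 0.0745). The myeloperoxidase gene mpx, at a log2 difference of -0.77 ± 0.34 (SE), did not pass (limma, adjusted p = 0.107), nor did its 3 other probe sets. It passed with array weights, at -1.10 (adjusted p = 0.0170), and without control arrays 3 and 5, at -1.22 (adjusted p = 0.0344). The group's mean level was 9.26 ± 0.52 against 10.27 ± 0.56 (SD, n = 5 each; exact permutation p = 0.0317, adjusted 0.113), and camera called it (limma, adjusted p = 0.00694). The call was lost with an estimated correlation (p = 0.181, adjusted p = 0.904). Without control arrays 3, 4 and 5 2 members passed and the median difference went from -0.83 to -1.34. CREB arrays 1, 2, 3 and 5, with neutrophil levels between 8.63 and 9.47, had kidney gene levels between 8.43 and 8.59. CREB array 4, with a kidney gene level of 7.67, had a neutrophil level of 10.03, inside the control range of 9.59 to 10.77. The control arrays did not show this inverse order. Control arrays 3 and 5 had the lowest neutrophil levels (9.72 and 9.59) and the lowest kidney levels (7.25 and 7.43). Control arrays 1 and 2 had the highest of both (10.64 and 10.77, 7.88 and 7.77).

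Among myeloid transcription factors and pan-leukocyte genes, 3 of 19 rose and 1 fell (3 and 0 adjusted over the list alone), and camera did not call the group (limma, adjusted p = 0.596), except without control arrays 3 and 5 or 3, 4 and 5, when it was lower (adjusted p = 0.0468 and 0.0498). The 3 that rose were klf4, by 0.74 ± 0.12 on the log2 scale, cebpd, by 2.47 ± 0.41, and cebpb, by 1.26 ± 0.25 (SE; limma, adjusted p = 0.00405, 0.00463 and 0.00859). All 3 encode transcription factors, and the last 2 act in granulocyte and macrophage gene expression. A second cebpd probe set, with a log2 difference of 0.15, did not pass. Without control arrays 3, 4 and 5 cebpd, at 2.37, and cebpb, at 1.01, did not pass (limma, adjusted p = 0.0781 and 0.112). The granulocyte factor gene cebpa and the myeloid factor gene spi1b, with log2 differences of 0.80 ± 0.36 and -0.76 ± 0.52 (SE), did not pass (limma, adjusted p = 0.110 and 0.277). Without CREB array 2 cebpa passed, at 1.05 (adjusted p = 0.0419), and without CREB array 4 spi1b passed, at -1.19 (adjusted p = 0.0458). The progenitor factor gene myb fell by 1.54 ± 0.42 (SE; limma, adjusted p = 0.0233), a call lost without control array 1, control array 4 or CREB array 5 (adjusted p up to 0.0527). Without CREB arrays 3 and 5, which had 6.05 and 6.08 against 7.13 to 7.93 on the other CREB arrays, the difference was -0.94 (adjusted p = 0.0942).

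**Figure D2:**
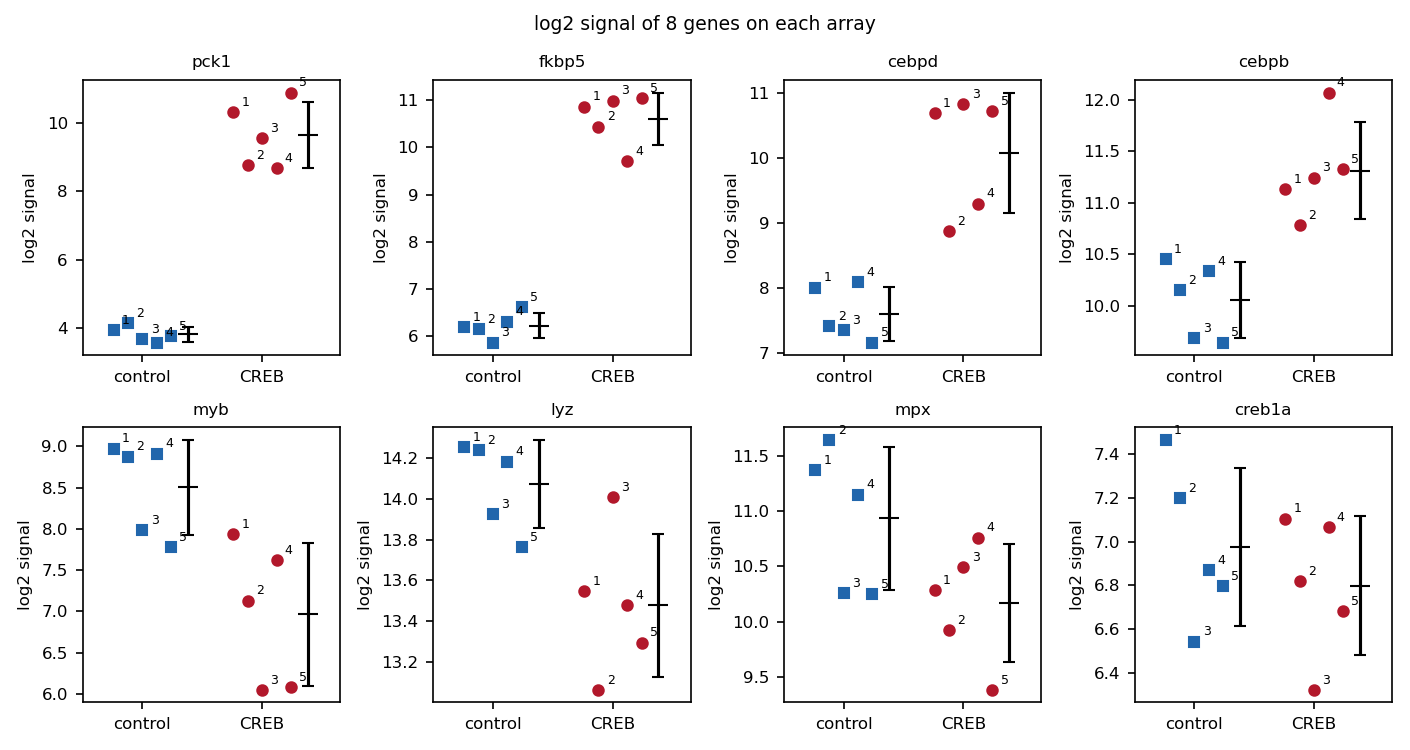
The log2 signal (y axis) of 8 genes on each array, by group (x axis); points are arrays numbered by replicate, and the bar at the right of each group gives the mean and SD of 5 arrays. For pck1, fkbp5, cebpd and cebpb the CREB arrays lie above the control arrays, for myb, lyz, mpx and creb1a the groups overlap, and each panel has its own scale, which does not start at 0.

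Camera called no other blood cell list in the comparison as designed (limma, adjusted p between 0.280 and 0.793). It called macrophage markers lower with array weights (adjusted p = 0.0419), and both macrophage and thrombocyte markers lower without control arrays 3 and 5 (adjusted p = 0.0247 and 0.0495) or 3, 4 and 5 (adjusted p = 0.0108 and 0.0409). These calls used the preset correlation, with which 66 of 100 splits of the arrays gave 8 or more called lists, so they decide nothing. Haematopoietic stem and progenitor cell genes went both ways, with 7 of 24 higher and 3 lower (12 and 3 adjusted over the list alone), and 4 higher under each of 3 other scalings. The homeobox gene hoxa9b rose by 0.73 ± 0.13 on the log2 scale and the Polycomb gene bmi1a fell by 1.13 ± 0.24 (SE; limma, adjusted p = 0.00643 and 0.00973). In control fish hoxa9b, at 4.09, was at the level of tag sequence probe sets (4.08), and without control arrays 3, 4 and 5 bmi1a was at -0.72 (adjusted p = 0.102). Of 11 macrophage and antigen-presenting cell markers only the protease gene ctss2.1 fell, by 2.19 ± 0.47 (SE; limma, adjusted p = 0.0110), also adjusted over the list alone. Thrombocyte markers had 3 of 6 lower (1 higher and 3 lower adjusted over the list alone), among them the adhesion gene selp, down by 1.56 ± 0.35 (SE; limma, adjusted p = 0.0121). Without CREB arrays 3 and 5 none of these markers passed, and without control arrays 3, 4 and 5 only 1 did. Of 6 B cell genes 2 were higher and 1 lower (2 and 2 adjusted over the list alone), and the recombinase gene rag2 rose by 0.47 ± 0.12 at a low signal of 5.34 (SE; limma, adjusted p = 0.0169). None of the 6 passed under quantile scaling, and under cyclic loess none was higher and 2 were lower. T and NK cell genes had 1 of 7 higher and 1 lower, also adjusted over the list alone, and none passed under quantile scaling. Erythroid genes had 2 of 25 higher and 1 lower, and none adjusted over the list alone; their median difference was 0.01, their mean -0.14, and camera's direction was down. The erythroid factor gene gata1a, with a log2 difference of 0.58 ± 0.35 (SE), did not pass (limma, adjusted p = 0.220). Only 2 mast cell and eosinophil markers were measured, too few for the camera test, and the protease gene cpa5 fell by 1.45 ± 0.34 (SE; limma, adjusted p = 0.0141), also adjusted over the list alone.

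The largest falls among genes free of overlap belonged to no single list. The genes viml, fabp7a, a fatty acid binding protein gene, and f13a1a.1, which encodes a subunit of coagulation factor XIII, had log2 differences of -3.33 ± 0.35, -3.13 ± 0.52 and -2.97 ± 0.56 (SE; limma, adjusted p = 0.000944, 0.00463 and 0.00732). In CREB fish fabp7a, f13a1a.1, pdia2 and lpcat4 were at 4.50, 4.51, 4.35 and 3.74, no higher than the remaining control probe sets (4.76), so the size of these falls, and their order among the largest, is limited by background. The others after pdia2 and srgn were ypel3, spink2.1, timp2b, lpcat4, rrbp1b, calr and serinc5, with log2 differences from -2.51 to -1.94. The lpcat4 call was lost without control array 5 or without CREB array 1, 2, 3 or 5 (adjusted p up to 0.0775), and its difference was -0.97 without control arrays 3, 4 and 5.

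With all arrays and probe sets on the deposited scale, camera called none of the remaining general programmes (limma, adjusted p between 0.280 and 0.825). Heat shock and protein-folding genes went both ways, with 9 of 36 higher and 8 lower (10 and 9 adjusted over the list alone). The cytosolic chaperone gene hsp90aa1.2 rose by 2.19 ± 0.35, while the endoplasmic reticulum genes calr3a, pdia4 and calr had log2 differences of -1.46 ± 0.18, -1.87 ± 0.30 and -1.96 ± 0.37 (SE; limma, adjusted p between 0.00168 and 0.00746). A second hsp90aa1.2 probe set, at 0.88, did not pass. Inflammatory response genes had 7 of 19 higher and 1 lower (7 and 2 adjusted over the list alone), led by cebpd and by junba, which rose by 1.98 ± 0.37 (SE; limma, adjusted p = 0.00719). In that list 3 were higher and 1 lower without CREB arrays 3 and 5, and none higher and 1 lower without control arrays 3, 4 and 5. Its median difference went from 0.31 to 0.02 without CREB array 4. P53 target and apoptosis genes had 5 of 30 higher and 3 lower, also adjusted over the list alone. The apoptosis inhibitor gene xiap rose by 0.98 ± 0.11 and the initiator caspase gene casp9 fell by 1.18 ± 0.15 (SE; limma, adjusted p = 0.00127 and 0.00191). Oxidative phosphorylation genes had 12 of 79 higher and 1 lower (6 and 0 adjusted over the list alone), with cyc1 higher by 0.99 ± 0.14 and sdha by 0.998 ± 0.19 (SE; limma, adjusted p = 0.00314 and 0.00737). Camera called that list higher under quantile scaling (adjusted p = 0.00255) and cyclic loess (adjusted p = 0.0245), but also on the deposited scale without the dimmest 40% of probe sets (adjusted p = 0.0254) or those of mean below log2 6 (adjusted p = 0.0105). The same held without CREB array 3, without control array 2, or without CREB arrays 3 and 5 (adjusted p = 0.0351, 0.0325 and 0.0114). All these calls used the preset correlation, with which 66 of 100 splits of the arrays gave 8 or more called lists. On all arrays with an estimated correlation camera did not call the list (p = 0.754, adjusted p = 0.926). Glycolysis and hypoxia genes had 3 of 36 higher (2 adjusted over the list alone), among them aldoab, up by 2.62 ± 0.36 (SE; limma, adjusted p = 0.00270). Ribosomal protein genes had 6 of 73 higher (1 adjusted over the list alone; 2 higher and 2 lower under cyclic loess) and interferon-response and antigen-presentation genes 2 of 21 (1 adjusted over the list alone). For the interferon list the median and mean difference were 0.05 and 0.06 while camera's direction was down.

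The remaining tissue lists were not called either with all arrays and probe sets (limma camera, adjusted p = 0.351, 0.280 and 0.280). Interrenal and chromaffin genes had 3 of 11 higher, among them nr5a1a and th, up by 0.996 ± 0.22 and 0.54 ± 0.13 on the log2 scale (SE; limma, adjusted p = 0.0126 and 0.0135). In control fish both were at or below the level of tag sequence probe sets (3.35 and 3.90, against 4.08), none of the 3 had a mean of log2 6 or more, and quantile scaling and cyclic loess left 1 call. Without CREB arrays 3 and 5 nr5a1a was at 0.65 (limma, adjusted p = 0.0238). Endothelial and stromal genes had 3 of 15 higher, among them col5a2a, up by 0.76 ± 0.19 (SE; limma, adjusted p = 0.0182). Both counts were the same adjusted over the list alone. None of 18 liver genes passed by either adjustment, and camera called the list higher only without control arrays 3, 4 and 5 (adjusted p = 0.0322). Endothelial and stromal genes were called higher only without probe sets of mean below log2 6, at a median of 0.80 (adjusted p = 0.0469). The liver call and this one used the preset correlation and decide nothing. With it, 66 of 100 splits of the arrays gave 8 or more called lists. The hemopexin gene hpxa was at 10.61 on CREB array 5 and between 4.83 and 6.25 on the other CREB arrays.

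Over all probe sets, 4692 of 15502 (30.3%) differed between the groups, 3640 higher and 1052 lower in CREB fish (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold, 714 were higher and 406 lower. The groups were free of overlap at 3696 probe sets (23.8%), against 0.794% by chance. The share of higher calls among all calls was 77.6% on the deposited values, 60.4% after quantile scaling, 63.3% after median centring and 51.9% after cyclic loess. The median difference over all probe sets was 0.18, and it was 0.04, 0.11 and -0.01 under those scalings. Subtracting 0.18 from a log2 difference gives the change relative to the median probe set, and none of the 92 named genes past the test changed sign by it or under the 3 scalings. Without control arrays 3, 4 and 5, which leaves 2 control arrays, 369 probe sets differed, 143 higher and 226 lower, and without CREB array 5 alone 3125 did, 609 of them lower.

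Signs of RNA quality and background differed between the arrays. The log2 difference between the 3' and 5' probe sets of gapdh, which grows as RNA is degraded, was 4.89 on CREB array 3 and 4.46 on CREB array 5, and between 1.06 and 1.53 on the other 8 arrays. The groups' means were 2.69 ± 1.82 and 1.25 ± 0.12 (SD, n = 5 each; exact permutation p = 0.0794, adjusted 0.125 over 11 classes of control probe sets). Without CREB arrays 3 and 5, 2034 probe sets differed, 1664 higher and 370 lower. Probe sets for Bacillus genes, which the fish lack, were at 3.83 ± 0.11 in CREB fish and 3.59 ± 0.06 in control fish (SD, n = 5 each; exact permutation p = 0.00794, adjusted 0.0175). Below a mean signal of log2 6, 2465 of 8097 probe sets were called higher and 230 lower, and at or above it 1175 of 7405 higher and 822 lower.

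**Figure D3:**
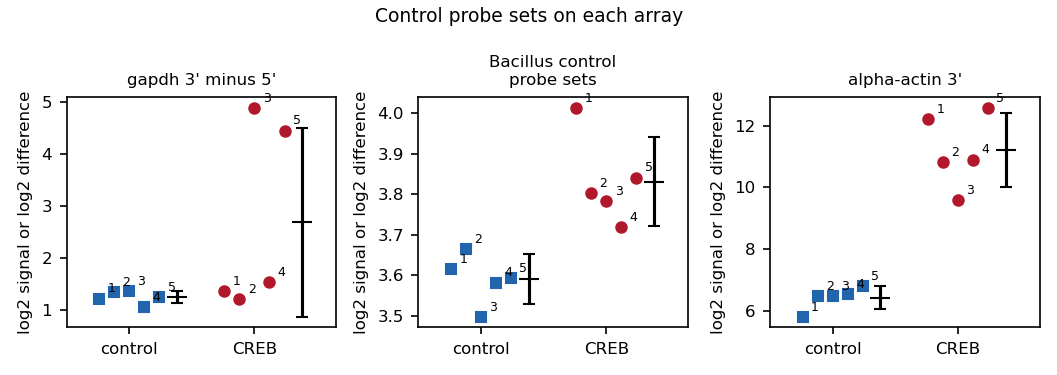
Control probe sets on each array, by group (x axis), as log2 signal or, for gapdh, the log2 difference between its 3' and 5' probe sets (y axis); points are arrays numbered by replicate, and the bar gives the mean and SD of 5 arrays. CREB arrays 3 and 5 stand at 4.89 and 4.46 for gapdh, and all 5 CREB arrays lie above the control arrays for Bacillus and alpha-actin probe sets. The alpha-actin probe set is for acta1, a skeletal muscle gene, and is no measure of background.

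The spread between fish did not differ detectably between the groups. The root mean square distance of each array from the mean of the other 4 of its group was 0.559 ± 0.068 in CREB fish and 0.605 ± 0.131 in control fish (SD, n = 5 each; exact two-sided permutation p = 0.508). Without control array 4 the difference was -0.13 (exact permutation p = 0.0317). The first principal component held 48.0% of the variance and separated the groups in its mean (exact permutation p = 0.0159), with control arrays 3 and 5 at its far end. CREB array 4 correlated best with control array 4 (Pearson's r = 0.950 across probe sets).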

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

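Tests of background signal, of degraded RNA, of egg RNA and on the separate muscle and glucocorticoid lists were chosen after the patterns they address were seen; the bounds for these 2 lists were set before the lists' own values, except that of pvalb3, were seen, and their members were matched again by synonyms afterwards. Of 292 groups of 5 arrays checked (named genes, list levels and distances between fish), 12 held an array far from the other 4, about the 5% that chance gives. On CREB arrays these were c1qc at 10.43 on array 4 (others 8.94 to 9.29), eomesa at 5.22 on array 2 (5.83 to 6.06), mycb at 6.81 on array 3 (7.50 to 7.70), angpt1 at 5.43 on array 1 (4.76 to 4.96) and hpxa at 10.61 on array 5 (4.83 to 6.25). Among list levels they were kidney genes at 7.67 on CREB array 4 (8.43 to 8.59), interrenal and chromaffin genes at 5.32 on CREB array 1 (4.57 to 4.72), and gonad and egg genes at 6.84 on CREB array 4 (5.33 to 5.76). On control arrays they were cpox at 7.99 on array 1 (8.46 to 8.57), angpt1 at 4.08, postnb at 6.64 and clocka at 5.28 on array 3 (4.34 to 4.40, 5.41 to 5.76 and 5.45 to 5.47).

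Some classes of control probe sets, which the comparisons do not use, carried a signal above every control array on every CREB array, while the older hybridization controls and the gapdh 5' and middle probe sets had a lower mean in CREB fish (8.18 against 9.50, 8.77 against 10.23 and 9.73 against 10.86). For the classes that were higher, the mean in CREB fish and the range on control arrays were 11.22 and 5.81 to 6.81 for alpha-actin, 3.83 and 3.50 to 3.66 for Bacillus genes, 10.76 and 9.67 to 10.23 for the r2 hybridization controls, 4.33 and 3.90 to 4.18 for tag sequences, and 4.76 and 4.23 to 4.46 for the remaining control probe sets. The alpha-actin probe set is for acta1, a skeletal muscle gene. Its difference of 4.79 stands beside the rises of the muscle genes and is no measure of background.

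CREB target and immediate-early genes were higher in CREB fish. A background rise of the measured size does not account for the whole rise. Their median difference of 1.02 (95% bootstrap interval 0.68 to 1.68) exceeds the rise of 0.25 in probe sets for absent sequences and of 0.39 in the remaining control probe sets. The bootstrap treats members as independent and takes no account of the spread between fish. The r2 hybridization controls rose by 0.71, inside the interval, and the median over all probe sets was 0.18. The older hybridization controls had a mean lower by 1.32, but not on every CREB array: arrays 3 and 5 were at 10.6 and 9.69. Degraded RNA does not account for the rise either, since without CREB arrays 3 and 5 the difference of the list's level was 1.22 (SE 0.17), with no overlap. A glucocorticoid or handling stress response stays open. A separate list of 24 genes had a median of 0.13 (interval -0.08 to 0.26, exact permutation p = 0.111). The bound written beforehand against this explanation, a median under 0.25, was met. The explanation was kept open because the interval reached past that bound, a stricter rule than the one written. Also, klf9 rose by 2.53 (limma, adjusted p = 0.00746), 5 of the 24 rose and 1 fell, and fkbp5, a known glucocorticoid target in no list, rose too. CREB overexpression itself, and other tissue on the same arrays where kidney and muscle transcripts were higher, stay open and were not tested as causes.

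Cell cycle genes were lower in CREB fish. Egg RNA in control arrays 3, 4 and 5 stays undecided as the whole cause or part of it. Without them the difference of the list's level was -0.39 (SE 0.31), between 1 and 2 SE from 0, against -0.88 (SE 0.30) with all arrays. Only 2 control arrays were left, and CREB array 4, with a raised gonad and egg level of 6.84, was kept. That array had the highest cell cycle level of the CREB arrays, at 7.60, so the removal was on 1 side only and cannot decide. The other CREB arrays, at 6.57 to 6.98, lay below control arrays 1 and 2, at 7.38 and 7.27. Degraded RNA is likewise undecided, at -0.66 (SE 0.36) without CREB arrays 3 and 5. An effect of CREB itself was not tested.

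Skeletal muscle genes were higher in CREB fish, and degraded RNA does not account for this, with a difference of 3.35 (SE 0.34) without CREB arrays 3 and 5. Muscle tissue in the CREB samples is a candidate explanation: in a second list of 25 muscle genes 19 rose and none fell (22 adjusted over the list alone; exact permutation p = 0.00794), but its median of 0.88 (interval 0.54 to 2.23) missed the bound of 1 set beforehand. Background limits the size of that median. In control fish klhl41b, whose difference is the median, was at 4.16, below the remaining control probe sets (4.36). The genes cacng1a, myod1, tnni2b.1 and myl1 were at 3.26, 3.49, 3.71 and 3.85, below tag sequence probe sets (4.08). In the same list pvalb3 was at 11.47 in CREB fish and 5.52 in control fish, while mb was at 11.07 and 11.08 and did not pass. The gene pvalb3 had already been seen among the largest rises. A rise within marrow cells cannot be told apart from carried-over tissue here, because no value measures the tissue content of a sample.

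Chance in the grouping of fish was tested on 100 splits of the 10 arrays drawn at random. It can be excluded for the number of probe sets that differ (4692, highest other split 62), that are higher (3640, 50), lower (1052, 50) and 2-fold different (1120, 58), each reached by 1 split, the real one. It cannot be excluded for the number of lists called by camera with a preset correlation. There, 66 of the 100 splits gave 8 or more, and the other splits had a median of 9 and a highest count of 16. Excluding chance leaves open a difference in sample or array handling that goes with the groups. The labels give no batch, so this was not tested. The r2 hybridization controls also differed without overlap, at 10.36 to 11.23 on CREB arrays and 9.67 to 10.23 on control arrays.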

How the results depend on the processing

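Leaving out arrays 3 and 5 or 3, 4 and 5, and the permutation of list levels, were chosen after seeing the data. The number of probe sets that differ (4692; 3640 higher, 1052 lower) was 2033 (1294 higher) without the dimmest 40% and 1526 (907 higher, 619 lower) without those of mean below log2 6, where fewer were tested. It was 2852 (1723 higher) with quantile scaling and 2837 (1473 higher) with cyclic loess, and 2001 were higher with median centring; the cause was not tested. Leaving out 1 array gave between 3125 (without CREB array 5) and 5163 (without CREB array 4), with 2474 to 3925 higher, 609 to 1238 lower and 875 to 1470 at least 2-fold. Without control arrays 3 and 5 the count was 2436 (1556 higher). Without control arrays 3, 4 and 5 it was 369 (143 higher, 226 lower, 299 at least 2-fold), and without CREB arrays 3 and 5 it was 2034 (1664 higher, 370 lower, 676 at least 2-fold); both have fewer arrays.

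With the replicate number as a block 2378 differed, 1762 higher and 616 lower. The numbers share no stated origin, and same-numbered arrays correlated at 0.204, 0.268, 0.047, -0.003 and -0.023 in their deviations from the group means. Only CREB array 2 correlated best with its own number.

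The 8 lists called became 0 with an estimated correlation (limma camera; lowest p 0.0522), 4 with fry and 0 with the exact permutation of list levels, where 3 lists had the smallest possible p of 0.00794 (adjusted 0.0661). Leaving out 1 array gave 6 to 9. Without control arrays 3, 4 and 5 the medians reversed for exocrine pancreas genes (0.996) and gonad and egg genes (0.47), the arrays with those transcripts being gone. The gene rpl3 reversed to -0.72 with the mean of its 2 probe sets, which differ in direction. No other named gene past the test reversed under any alternative. Of 92, 60 lost the call without control arrays 3, 4 and 5, 26 without CREB arrays 3 and 5, 20 with the block, and 10 to 13 under the 3 scalings.

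The spread between fish (CREB minus control -0.05) ranged from -0.133 to -0.00226 with 1 array left out and passed only without control array 4 (-0.13, exact permutation p = 0.0317; cause not tested). The gene creb1a passed under no alternative, but its value moved. It was between -0.28 and -0.05 with 1 array left out, 0.02 without CREB arrays 3 and 5, and -0.53 without control arrays 3, 4 and 5. Signal over background limits the dim probe sets, where background differed between groups.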

Other observations

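Some values bear on no comparison of the design. A control probe set for EGFP was at 7.10 ± 0.30 in CREB fish and 6.67 ± 0.28 in control fish (SD, n = 5 each; exact permutation p = 0.0317, adjusted 0.0582), with overlapping ranges of 6.80 to 7.60 and 6.22 to 6.99. The labels do not say whether either line carries a fluorescent reporter.

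The older hybridization control probe sets, which measure transcripts added to each sample, were at 8.18 ± 1.98 in CREB fish and 9.50 ± 0.28 in control fish (SD, n = 5 each; exact permutation p = 0.159), while the r2 versions went the other way by 0.71. The older ones split within the CREB group. They were at 7.20, 7.71 and 5.67 on CREB arrays 1, 2 and 4, and at 10.6 and 9.69 on CREB arrays 3 and 5, against 9.03 to 9.71 on control arrays.

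Genes of the glucocorticoid-responsive list given here, and klf9, were chosen after their values were seen. Besides klf9, the cortisol-inactivating enzyme gene hsd11b2 rose by 1.48 (limma, adjusted p = 0.0180), the gluconeogenic gene g6pc1a.2 by 1.38 (adjusted p = 0.0294), and fam107b fell by 1.26 (adjusted p = 0.0277). The glucocorticoid receptor gene nr3c1, at 0.25, did not pass (adjusted p = 0.376), and neither did tsc22d3, at 0.12 (adjusted p = 0.714).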
